A study of Homo sapiens with 6 samples.

How the data were processed

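Total RNA from HEK293 cells was made into libraries with an mRNA preparation kit, per the labels' protocols, 48 h after transfection of 158 ng of plasmid per square centimetre. The samples fell into 2 groups of 3 libraries, PKI and inPKI, by their titles, and the letters A, B and C name the libraries within a group. Nothing states that a letter marks a shared day or culture.

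The submitters' processing notes name cutadapt 1.14, STAR 2.5.2b, RSEM 1.3.0, DESeq2 1.20.0 and the build hg19, with no role, order or setting. The authors deposited 1 table of CPM for 30960 genes and the 6 libraries, and the columns sum to 754299 to 785007. Its name gives RSEM, CPM, TMM and counts, taken here as RSEM counts scaled by library size and TMM factors. The table holds no coordinates. The other deposited table is the authors' own comparison, and per the file headers it gives a mean signal (baseMean), a log2 fold change with its standard error, a Wald statistic (a score), a p-value, an adjusted p-value and a signed fold change. In all 30960 rows of the authors' deposited table the log2 fold change has the opposite sign to the signed fold change, and against the CPM it is positive where inPKI is higher, so it is printed here with its sign turned to PKI over inPKI. In 2069 genes that are 0 in all 6 libraries the baseMean is above 0, so the authors' deposited table rests on more libraries than the 6 analysed here.

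Every deposited CPM value (100%, within a tolerance of 0.01 reads) was a whole multiple of the smallest value in its column. Whole reads were recovered by that division, 17244715 to 23589438 per library, and 1 read is worth 0.0333 to 0.0437 CPM. These reads may be rounded RSEM estimates, which cannot be told from the values. PCR duplicates cannot be told apart, and counting error is the least error a value carries.

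The test was fixed before the data were examined. Values were taken as log2(CPM + 1), which understates the change of low genes, for the 14275 genes with a CPM of at least 1 in at least 3 of the 6 libraries. A linear model was fitted with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend, 2-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Every adjusted p in the text comes from limma unless another tool or the authors' deposited table is named. Log2 changes are PKI minus inPKI, with the moderated standard error. With 3 libraries against 3, an exact permutation test of 1 value cannot go below 0.1.

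Before the data were examined, 24 gene lists were fixed from textbook knowledge, of which 22 had at least 5 genes tested. They cover CREB-responsive genes, PKA subunits with PKI genes and anchoring proteins, cAMP synthesis and breakdown, ERK output, Hedgehog, YAP-TEAD, SRF-actin, S phase, G2 and mitosis, p53, interferon, NF-kB, the unfolded protein response, heat shock, cholesterol, glycolysis, Wnt, neuronal genes, mitochondrial mRNAs, ribosomal proteins, histones, and keratinocyte, fibroblast and leukocyte markers. Each was tested with limma's camera (preset correlation 0.01), adjusted over the 22 lists, with the estimated correlation beside it, and with fry. Camera with an estimated correlation called 0 of the 22 lists and was not tried on simulated counts. Its lack of a call alone therefore does not speak against a list. Counts adjusted over the list alone use the members' p-values only.

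Genes were named by a rule set before the data were examined. PKIA, PKIB, PKIG, PRKACA, PRKACB and PRKAR1A are always named. The 8 largest increases and the 8 largest decreases follow, among genes at adjusted p below 0.05 with a mean of at least 5 CPM and groups that do not overlap. From each list come up to 3 members with the smallest p among those past the threshold, or, where none passed, the member with the smallest p. A gene in a set of 5 or fewer may be named when it is said to be chosen after its values were seen.

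Positions, gene types, transcript lengths and GC content come from GENCODE 29 on GRCh38, looked up by gene identifier. Of the identifiers 30795 matched and 165 did not, and 99.8% of tested genes had a length. The notes name hg19, so these positions are those of the annotation and not of the authors' alignment.

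The alternatives fixed beforehand were pseudocounts of 0.25 and 5, no filter on low values, a filter of 5 CPM, median-ratio rescaling, rescaling to an equal sum, a replicate block, limma without a trend, limma with sample weights, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, and leaving out each library in turn. Added after seeing the data were the removal of trends of transcript length and GC content (lowess, span 0.3), leaving out PKI A and PKI C together, and counting identical rows once. Figures were drawn with matplotlib 3.10.9.

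The tests were tried on simulated counts for PKI against inPKI over the 14275 genes, in 5 draws that each changed 200 genes. With limma, 43.5% of the genes changed 1.25-fold were recovered, 77.5% of those changed 1.5-fold, 93.5% at 2-fold and 100% at 4-fold, and 9.03% of the calls were genes that had not been changed. For edgeR that share was 8.70% and for DESeq2 7.21%. In 20 draws with the ERK list raised by 0.3 (log2), camera called it in 20, and it called 2 of 408 tests of lists that share no member with it. The simulated genes varied independently of each other. In the data the estimated correlation within a list was 0.75 for the ribosomal proteins, 0.91 for the mitochondrial mRNAs and 0.15 for the ERK list. The median log2 change of the ERK list was 0.12, below the simulated 0.3. Neither the 20 calls in 20 draws nor the simulated share of false list calls therefore carries over to these lists.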

Results

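RNA was sequenced from HEK293 cells, a human embryonic kidney cell line, 48 h after transfection with a plasmid for a fusion of GFP with either PKI1-24 or inPKI1-24, the latter being the control in the labels. PKI is a family of small proteins that bind the catalytic subunit of protein kinase A (PKA), the cAMP-dependent kinase, and block it. Each group held 3 libraries, named A, B and C. The reads recovered from the deposited CPM came to 20088703, 21387137 and 18707086 in inPKI A, B and C, and to 21202701, 23589438 and 17244715 in PKI A, B and C. Of 30960 genes in the table, 14275 entered the tests. Nothing in the labels says that the libraries came from separate cultures, so the p-values measure only the spread among these libraries, which may be technical.

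The first comparison was of the PKI genes themselves, to see whether the libraries separate by their labels. PKIA, which encodes the alpha form of PKI, measured 9.68 ± 1.46 CPM in inPKI and 43.9 ± 1.96 CPM in PKI (SD, n = 3 each). Its log2 change, PKI minus inPKI on the log2(CPM + 1) scale, was 2.08 ± 0.088 (SE), with an adjusted p of 5.64e-09, and each of the 3 PKI libraries lay above each of the 3 inPKI libraries. The gene (ENSG00000171033.12) lies on chromosome 8, 78516139 to 78605267 in GRCh38. Counts per gene do not separate reads of a plasmid from reads of the cells' own PKIA transcript, and the sequences of the 2 inserts were not examined. This value therefore shows that the libraries separate by their labels, and it does not measure the cells' own gene. The other PKI genes did not pass the threshold: PKIB measured 7.33 ± 1.01 CPM in inPKI and 6.59 ± 1.58 CPM in PKI, and PKIG measured 9.20 ± 0.126 CPM in inPKI and 8.56 ± 0.554 CPM in PKI (SD, n = 3 each), with adjusted p of 0.653 and 0.652. The PKA subunit genes did not pass either. The catalytic subunit gene PRKACA had a log2 change of -0.10 ± 0.069 (SE, adjusted p = 0.521), its relative PRKACB 0.012 ± 0.076 (adjusted p = 0.962) and the regulatory subunit gene PRKAR1A -0.055 ± 0.051 (adjusted p = 0.653).

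The second comparison asked which genes differ in RNA level between cells with PKI and cells with the control fusion. Besides PKIA, the genes higher in PKI included the immediate early transcription factor EGR1, the stress-inducible chaperones HSPA6 and DNAJB1, and FLNC, which encodes the actin cross-linker filamin C. EGR1 measured 14.3 ± 2.40 CPM in inPKI and 28.4 ± 4.20 CPM in PKI (SD, n = 3 each), with a log2 change of 0.95 ± 0.11 (SE). HSPA6 measured 41.6 ± 2.33 CPM in inPKI and 77.7 ± 6.91 CPM in PKI, a log2 change of 0.88 ± 0.067. FLNC measured 59.1 ± 0.241 CPM in inPKI and 97.9 ± 2.93 CPM in PKI, a log2 change of 0.72 ± 0.051, and DNAJB1 measured 152 ± 7.44 CPM in inPKI and 204 ± 12.4 CPM in PKI, a log2 change of 0.42 ± 0.060. FOSL1, which encodes the AP-1 subunit FRA1, went from 2.23 to 4.92 CPM, a log2 change of 0.86 ± 0.13. KIF1A, a kinesin motor of axonal transport, had a smaller log2 change of 0.43 ± 0.068.

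The limma adjusted p was 0.00198 for EGR1 (ENSG00000120738.7, chromosome 5, 138465490 to 138469315 in GRCh38), 7.92e-06 for HSPA6 (chromosome 1, 161524540 to 161526910) and 4.19e-06 for FLNC (chromosome 7, 128830377 to 128859274). It was 0.00848 for DNAJB1 (chromosome 19, 14514770 to 14529770), 0.0127 for FOSL1 (chromosome 11, 65892049 to 65900573) and 0.0220 for KIF1A (chromosome 2, 240713761 to 240821036). In each of these genes all 3 PKI libraries lay above all 3 inPKI libraries. HSPA6 has a near-identical neighbouring copy, HSPA7, and the counting could split reads between them.

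Another 4 genes higher in PKI fell below the mean of 5 CPM set for naming and were chosen after their values were seen. The cytokine gene IL11 rose from 0.270 ± 0.0508 to 1.83 ± 0.315 CPM (SD, n = 3 each), which was 6 to 9 reads per inPKI library and 46 to 50 per PKI library, with an adjusted p of 0.00837. MAFF, a small MAF transcription factor gene, measured 3.18 ± 0.477 CPM in inPKI and 6.38 ± 0.233 CPM in PKI, with an adjusted p of 0.00848. SULT1A4 and C5orf66 had log2 changes of 1.24 ± 0.22 and 0.92 ± 0.16 (SE), with adjusted p of 0.0490 and 0.0435. SULT1A4 has a near-identical copy, SULT1A3, and C5orf66 is annotated as antisense, so the reads of both are uncertain. SULT1A4 did not pass without inPKI B (0.160), inPKI C (0.0733), PKI B (0.0509) or PKI C (0.0636), given as adjusted p, in a range of 0.00518 to 0.333 over the alternatives. C5orf66 did not pass without inPKI A (0.190), inPKI C (0.135), PKI A (0.0665) or PKI C (0.0604), in a range of 0.0123 to 0.333.

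The remaining called genes share sequence with other genes, and their reads are uncertain for that reason. Among them SMG1P3, PKD1P1 and RGPD8 were higher in PKI, by 0.52 ± 0.081, 0.48 ± 0.083 and 0.44 ± 0.076 (log2, SE); the first pair are pseudogenes and RGPD8 belongs to a family of recent copies. All 4 genes lower in PKI are of this kind. The ribosomal protein pseudogenes RPS7P1 and RPL41P2 had log2 changes of -0.50 ± 0.086 and -0.38 ± 0.065, the processed pseudogene RP11-553P9.1 -0.40 ± 0.059 and the read-through gene NME1-NME2 -0.49 ± 0.081 (SE). Leaving out 1 inPKI library ended most of these calls. Without inPKI A, B and C the adjusted p was 0.190, 0.208 and 0.0929 for RGPD8 (range over the alternatives 0.00152 to 0.320), 0.0910, 0.123 and 0.135 for PKD1P1 (0.000300 to 0.333), 0.0994, 0.170 and 0.141 for RPS7P1 (0.00479 to 0.307) and 0.190, 0.0587 and 0.0929 for NME1-NME2 (0.000106 to 0.333). RP11-553P9.1 did not pass without inPKI A (0.0997) or inPKI B (0.0851; 4.08e-05 to 0.192), nor RPL41P2 without inPKI B (0.170) or inPKI C (0.150; 0.00102 to 0.295).

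In all, 18 genes passed an adjusted p of 0.05 in limma, 14 higher and 4 lower in PKI, and 3 of them (PKIA, IL11 and SULT1A4) had an absolute log2 change of at least 1. The 1 added to each CPM shrinks the log2 change of low genes, and by the ratio of mean CPM 6 of them differed at least 2-fold (FOSL1, MAFF and C5orf66 as well). At an unadjusted p below 0.05 there were 1954 of the 14275 genes tested, 1075 higher and 879 lower. The counts at that level in the gene lists below are to be read against this share. The groups did not overlap in 2817 genes, 19.7% of those tested, where chance gives 10%. With the columns rescaled to an equal sum the split was 10 higher and 1 lower, against 14 and 4 as reported. Leaving out 1 library gave 114 genes without PKI B, 46 without PKI C, 37 without PKI A, 11 without inPKI A and 9 without inPKI B. Calls lost that way, with the adjusted p without the library, were DNAJB1 without inPKI A (0.0910) or inPKI B (0.0946) and FOSL1 without inPKI A (0.0575) or inPKI B (0.0701). KIF1A was lost without inPKI B (0.160) or inPKI C (0.101), and SMG1P3 without inPKI B (0.0946). Over all alternatives the adjusted p ranged over 6.22e-09 to 0.178 for DNAJB1, 0.000238 to 0.333 for FOSL1, 0.000668 to 0.171 for KIF1A and 0.000106 to 0.242 for SMG1P3. The calls of PKIA, HSPA6, FLNC, EGR1, IL11 and MAFF stood with any 1 library left out. With no filter on low values, and likewise with limma without a trend, only PKIA, HSPA6, FLNC and IL11 passed. Once trends of transcript length and GC content were removed, an alternative chosen after seeing the data, 9 of the 14 higher calls and 0 of the 4 lower calls were kept.

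**Figure D1:**
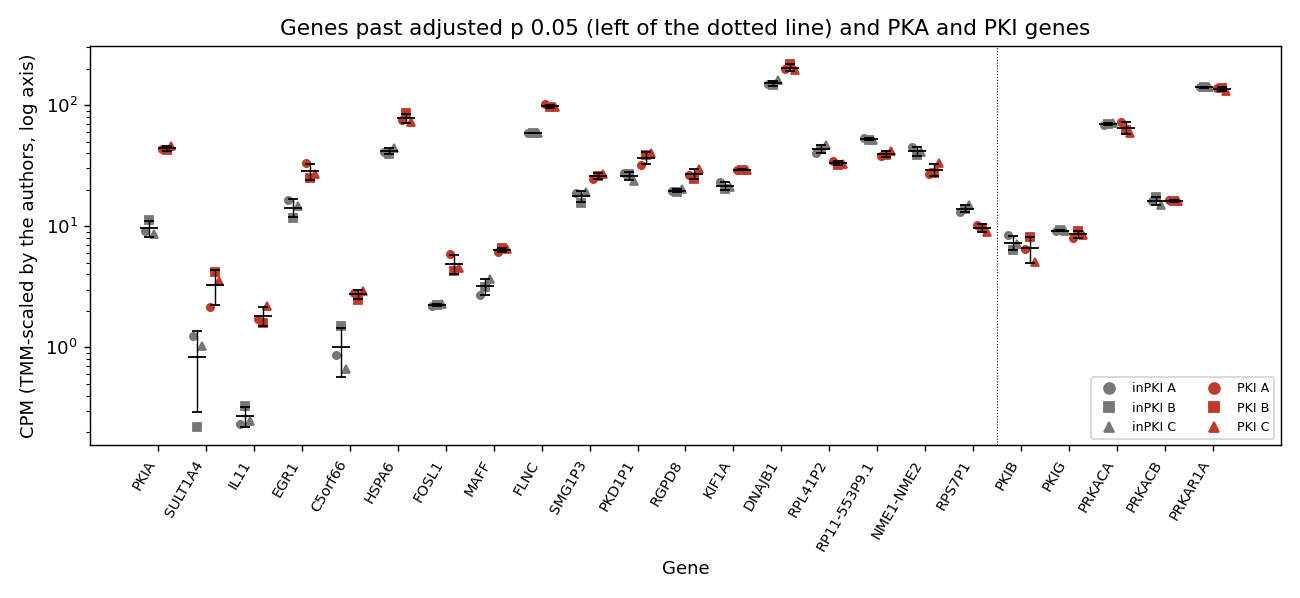
CPM of each library (log axis) for the 18 genes past an adjusted p of 0.05, left of the dotted line, and for 5 PKI and PKA genes that did not pass, with gray points for inPKI, red points for PKI, and black bars for the mean ± SD of 3 libraries. PKIA lies at 8.65 to 11.3 CPM in the inPKI libraries and at 42.3 to 46.1 CPM in the PKI libraries.

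The third comparison was of gene lists fixed before the data were examined, beginning with the pathway that PKI acts on. Of 21 tested CREB-responsive genes, which PKA switches on through the transcription factor CREB, 0 passed the threshold, and the list as a whole did not pass either (camera adjusted p = 0.254, median log2 change 0.033). By fry the adjusted p of the list was 0.791 for 1 direction and 0.00768 in the mixed test. At an unadjusted p below 0.05 limma gave 4 of these genes, against 1954 of all 14275 genes tested. Past the threshold edgeR gave 0 and DESeq2 1. The member with the smallest p was the phosphatase gene DUSP1, with 33.8 ± 2.51 CPM in inPKI and 42.7 ± 3.98 CPM in PKI (SD, n = 3 each) and an adjusted p of 0.110. Adjusted over the list alone, DUSP1 and the phosphodiesterase gene PDE10A (chosen after its values were seen, log2 change 0.35 ± 0.094, SE) were higher, and 0 were lower. DUSP1 passed the threshold over all genes without PKI C (adjusted p = 0.0267), with sample weights (0.0123) and by DESeq2 (0.0205), and, in alternatives chosen after seeing the data, with the length trend removed (0.0459), with the length and GC trends removed (0.0366) and without PKI A and PKI C (0.00385), in a range of 0.00385 to 0.485 over the alternatives.

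In the list of ERK pathway output and feedback genes, which follow mitogen-activated kinase signalling, 2 of 20 tested members rose in limma (EGR1 and FOSL1, also the 2 past the threshold by edgeR and by DESeq2), 0 fell and 18 did not pass. At an unadjusted p below 0.05 limma gave 4 of the 20, EGR1 and FOSL1 included, against 1954 of all 14275 genes tested. The list as a whole was higher in PKI (camera adjusted p = 0.000135, median log2 change 0.12), with 18 members above 0 and 2 below. The call was lost with an estimated correlation (adjusted p = 0.787) and by fry (adjusted p = 0.133). Adjusted over the list alone 3 were higher, the third being SPRY4, a feedback inhibitor of the pathway that was chosen after its values were seen, at 0.622 ± 0.00223 CPM in inPKI and 1.47 ± 0.278 CPM in PKI (SD, n = 3 each). The inPKI SD lies below the worth of 1 read there (0.0365 to 0.0414 CPM) and understates the counting error. The stricter filter of 5 CPM leaves out FOSL1, SPRY4 and other low members. With it the list's median was 0.045 and the list did not pass (camera adjusted p = 0.0618). Over all alternatives with the preset correlation its adjusted p ranged from 5.66e-06 to 0.0618.

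Among the 19 PKA subunit, PKI and anchoring protein genes, 1 rose in limma (PKIA), 0 fell and 18 did not pass. At an unadjusted p below 0.05 limma gave 5 of the 19, PKIA included. Past the threshold edgeR gave 1 and DESeq2 3, the other 2 being AKAP12 (adjusted p = 0.00956) and AKAP13 (adjusted p = 0.0296), both higher. The list was called higher by camera with the preset correlation (adjusted p = 0.0443, median log2 change -0.0096) and by fry (adjusted p = 0.0219). It was not called by camera with an estimated correlation (adjusted p = 0.787). That estimate was -0.038, below the preset 0.01, so correlation among the members does not account for the loss. Without PKIA the list's adjusted p in camera with the preset correlation was 0.285, and fry was not run without PKIA. Adjusted over the list alone 5 were higher, namely PKIA and the anchoring protein genes AKAP9, AKAP11, AKAP12 and AKAP13, which were chosen after their values were seen. Of 23 genes of cAMP synthesis, breakdown and EPAC, 0 passed in limma over all genes or adjusted over the list alone (5 at an unadjusted p below 0.05, 0 past the threshold by edgeR and by DESeq2), and the list was called higher by camera with the preset correlation (adjusted p = 0.0443, median 0.054), but not with an estimated one (adjusted p = 0.787) or by fry (adjusted p = 0.133). Its smallest p was that of the adenylyl cyclase gene ADCY1, with a log2 change of 0.21 ± 0.065 (SE, adjusted p = 0.189). The PKA list also did not pass without inPKI C (adjusted p = 0.0647) or without PKI B (0.0509). The cAMP list did not pass without inPKI A (0.0755), inPKI B (0.0800), PKI A (0.112), PKI B (0.0875) or PKI C (0.0593). The median of the PKA list was 0.016 without inPKI A, 0.013 without inPKI B and 0.021 without PKI C, and that of the cAMP list 0.087 without inPKI C and 0.086 without PKI C. Both calls were also lost in alternatives chosen after seeing the data: with the trend of transcript length removed the adjusted p was 0.225 for the PKA list and 0.714 for the cAMP list (median 0.035), with the GC trend removed 0.0710 and 0.0643, and with both removed 0.178 and 0.761 (median of the cAMP list 0.041). The length trend runs with the groups, so removing it may also take away an effect of PKI. Over the alternatives with the preset correlation the adjusted p ranged over 4.93e-07 to 0.225 for the PKA list and 0.0235 to 0.761 for the cAMP list.

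In the heat shock chaperone list 1 of 15 members rose in limma (DNAJB1), 0 fell and 14 did not pass. At an unadjusted p below 0.05 limma gave 4 of the 15, DNAJB1 included. Past the threshold edgeR gave 1 and DESeq2 2, the second being HSPA1B (adjusted p = 0.00831), chosen after its values were seen. Adjusted over the list alone 2 were higher, DNAJB1 and HSPA1A, another inducible chaperone gene that was chosen after its values were seen. The list's median log2 change was -0.051, while its mean (0.016) and the direction of its test were above 0 (camera adjusted p = 0.774). In the unfolded protein and integrated stress response list 0 of 25 passed in limma (3 at an unadjusted p below 0.05; past the threshold edgeR gave 0 and DESeq2 1), with no call of the list (camera adjusted p = 0.382), and adjusted over the list alone 1 was higher, the cystine transporter gene SLC7A11, at 34.8 ± 1.96 CPM in inPKI and 43.5 ± 1.67 CPM in PKI (SD, n = 3 each, adjusted p over all genes = 0.0722 in limma). SLC7A11 passed over all genes with the 5 CPM filter (adjusted p = 0.0462), the replicate block (0.0285), sample weights (0.0222) and DESeq2 (0.0110), in a range of 0.0110 to 0.442 over the alternatives.

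The proliferation lists did not pass. In the S phase list 0 of 22 genes passed in limma, as by edgeR and DESeq2, and 0 at an unadjusted p below 0.05. Of its genes 20 had a log2 change below 0, and the camera adjusted p was 0.206; without PKI B the list was called lower with the preset correlation and not with an estimated one (adjusted p = 0.714 with the latter; with the former adjusted p = 0.0176, median -0.076, range over the alternatives 0.0176 to 0.711). PCNA, the replication clamp, had a log2 change of -0.12 ± 0.066 (SE). In the G2 and mitosis list 0 of 24 passed in limma (3 at an unadjusted p below 0.05, and past the threshold 0 by edgeR and 2 by DESeq2; camera adjusted p = 0.382), and MKI67, a marker of cycling cells, had the smallest p, at 0.25 ± 0.068 (SE, adjusted p = 0.157, and 0.0441 without PKI B and 0.0139 by DESeq2, range over the alternatives 0.0139 to 0.545). In the p53 target list 0 of 20 passed in limma (2 at an unadjusted p below 0.05, 0 by edgeR and DESeq2; camera adjusted p = 0.774), with TP53I3 at -0.30 ± 0.094 (SE). For none of these lists was a gene higher or lower when adjusted over the list alone.

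The other signalling and identity lists did not pass in camera either. The adjusted p was 0.594 for 19 Hedgehog-GLI genes, where GPR161 had a log2 change of 0.25 ± 0.075 (SE), and 0.382 for 21 YAP-TEAD targets, where FJX1 had -0.22 ± 0.076. It was 0.594 for 15 SRF-actin genes (TPM2, 0.24 ± 0.10), 0.382 for 13 Wnt targets (APCDD1, 0.34 ± 0.13) and 0.254 for 11 neuronal genes (NEFL, -0.19 ± 0.057). It was 0.901 for 11 type I interferon genes (IFIT1, -0.23 ± 0.12), 0.440 for 8 NF-kB genes (TNFAIP3, 0.16 ± 0.11), 0.304 for 23 cholesterol genes (PMVK, -0.19 ± 0.071) and 0.382 for 27 glycolysis and hypoxia genes (ENO2, 0.38 ± 0.10). In these lists 0 genes passed over all genes tested in limma, edgeR or DESeq2, with 0 to 5 genes per list at an unadjusted p below 0.05, and adjusted over the list alone only the neuronal list held a call, with 1 gene (NEFL) lower. The fibroblast list (4 genes tested) and the leukocyte list (3 genes tested) were too small for the list test, and 0 of their genes passed in limma, edgeR or DESeq2 (0 at an unadjusted p below 0.05); COL5A1 had a log2 change of -0.11 ± 0.080 and CORO1A of 0.12 ± 0.11 (SE).

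**Figure D2:**
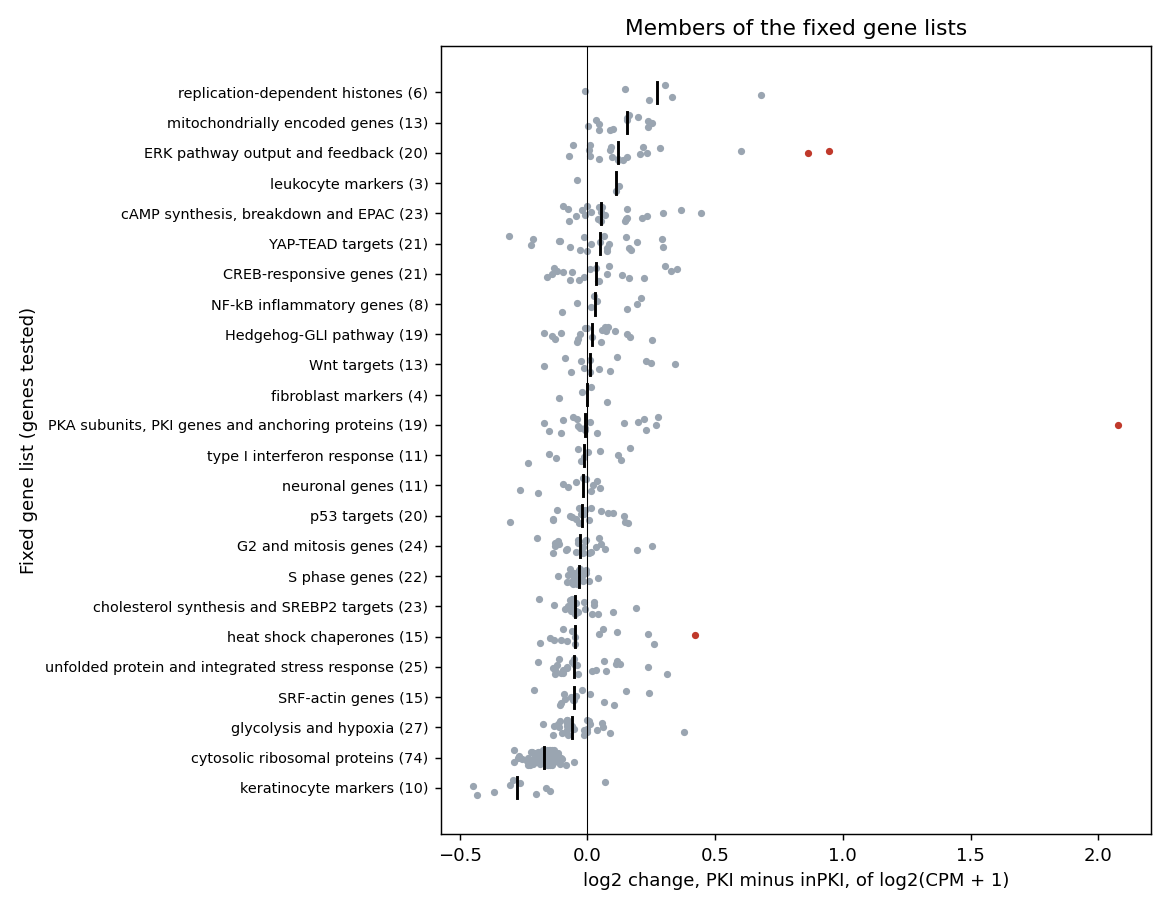
Log2 change, PKI minus inPKI on the log2(CPM + 1) scale, of each tested member of the 24 fixed lists, with the number of genes tested in brackets, red points for genes past an adjusted p of 0.05 and a black bar for the list's median. The ribosomal protein list has 74 of 74 members below 0, and the ERK list has 18 of 20 above 0.

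Genes for the cytosolic ribosome were called lower in PKI as a list by camera with the preset correlation (adjusted p = 1.71e-23), but not with an estimated one (adjusted p = 0.787) or by fry (adjusted p = 0.283). All 74 tested ribosomal protein genes had a log2 change below 0, from -0.29 to -0.053, with a median of -0.17. Of these 0 passed over all genes tested in limma (45 at an unadjusted p below 0.05, and past the threshold 0 by edgeR and 11 by DESeq2), and adjusted over the list alone 11 were lower. RPS21, which had the smallest p, measured 163 ± 2.77 CPM in inPKI and 136 ± 10.7 CPM in PKI (SD, n = 3 each, adjusted p = 0.119), and passed without PKI B (adjusted p = 0.0162), with the replicate block (0.0369), with sample weights (0.0222) and by DESeq2 (0.0114), in a range of 0.0114 to 0.478 over the alternatives. The median of the list against the inPKI mean was -0.14 in PKI A, -0.070 in PKI B and -0.30 in PKI C. Without PKI C the median of the list was -0.10 (adjusted p = 2.43e-36 with the preset correlation and 0.402 with an estimated one). Shorter transcripts were lower in every PKI library, and with the trends of transcript length and GC content removed, an alternative chosen after seeing the data, the median was -0.10 (adjusted p = 5.85e-23 with the preset correlation and 0.658 with an estimated one). Over the alternatives with the preset correlation the adjusted p ranged over 3.26e-46 to 3.90e-17.

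The mitochondrially encoded mRNAs and the replication-dependent histone genes were called higher in PKI by camera with the preset correlation, and the keratinocyte markers lower, but with an estimated correlation (adjusted p = 0.913 for each list) and by fry (adjusted p = 0.791, 0.787 and 0.791) all 3 calls were lost. All 13 mitochondrial mRNAs had a log2 change above 0 (median 0.15, camera adjusted p = 0.0387), as had 5 of 6 tested histone genes (median 0.27, adjusted p = 0.0443), while 9 of 10 keratinocyte genes were below 0 (median -0.28, adjusted p = 0.0443). In these 3 lists 0 genes passed over all genes tested in limma, edgeR or DESeq2, with 1, 1 and 0 at an unadjusted p below 0.05. Adjusted over the list alone 1 histone gene was higher, HIST1H2AG, at 0.922 ± 0.209 CPM in inPKI and 2.16 ± 0.976 CPM in PKI (SD, n = 3 each), and without PKI B it passed over all genes (adjusted p = 0.0480, range over the alternatives 0.0480 to 0.784). MT-ND4L had a log2 change of 0.24 ± 0.10 and KRT16, a keratin gene, -0.45 ± 0.23 (SE).

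Each of these list calls was lost without certain single libraries. The mitochondrial list did not pass without PKI C (adjusted p = 0.687), inPKI A (0.179) or inPKI B (0.0639). The histone list did not pass without PKI C (0.727), PKI A (0.0732), inPKI B (0.0644) or inPKI C (0.0647). The keratinocyte list did not pass without inPKI C (0.797), PKI C (0.197) or PKI B (0.134). The medians moved most without PKI C for the mitochondrial list (5.98e-05) and the histone list (0.067, and 0.43 without PKI B), and without inPKI C for the keratinocyte list (0.0030, with -0.43 without inPKI A and -0.50 without inPKI B). With the length trend removed, an alternative chosen after seeing the data, the mitochondrial and histone lists passed (adjusted p = 2.65e-08 and 0.00160) and the keratinocyte list did not (0.0713); with the GC trend removed the mitochondrial list passed (0.0456) and the histone and keratinocyte lists did not (0.0836 and 0.0902). Over the alternatives with the preset correlation the adjusted p ranged over 2.39e-08 to 0.687 for the mitochondrial list, 1.78e-06 to 0.727 for the histone list and 0.000103 to 0.797 for the keratinocyte list. The 12 keratinocyte genes at a near-fixed share of the authors' mean signal summed to 93.4 CPM in inPKI C and to at most 46.8 CPM in any other library. Ribosomal RNA, 7SL, 7SK, RMRP and snoRNA, which as a class lack a long poly(A) tail, stood apart in PKI A and PKI C. The median log2 difference of 10 such RNAs from the inPKI mean was 1.58 in PKI A and 2.43 in PKI C, against 0.099 in PKI B and -0.22 to 0.15 in the inPKI libraries.

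Longer transcripts were relatively higher in PKI. Across tested genes, which are not independent replicates, the Spearman correlation between a library's log2 difference from the inPKI mean and the length of the gene's longest transcript was 0.334 in PKI A, 0.335 in PKI B and 0.404 in PKI C. In the inPKI libraries it was 0.0271, -0.105 and 0.0726. With the genes in 5 groups of near-equal size by length, the median log2 difference in the group of the shortest transcripts was -0.063, -0.046 and -0.18 in PKI A, B and C, and in the group of the longest it was 0.070, 0.074 and 0.077.

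**Figure D3:**
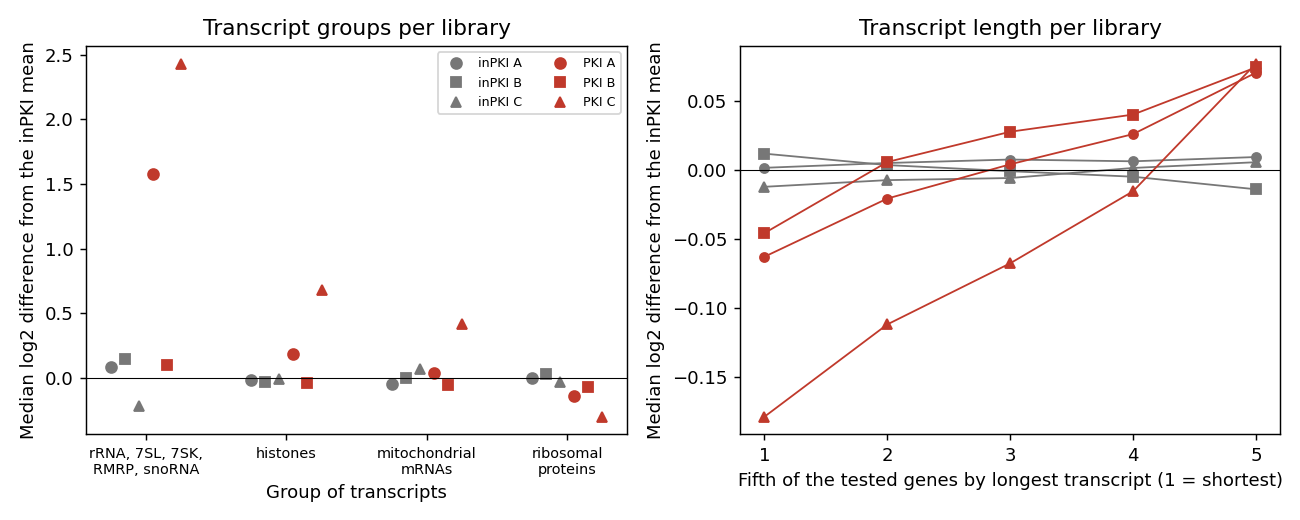
Median log2 difference of each library from the inPKI mean, on the left for 4 groups of transcripts and on the right for 5 groups of the tested genes by their longest transcript, with gray for inPKI and red for PKI. PKI A and PKI C stand at 1.58 and 2.43 for the RNAs without a poly(A) tail, and all 3 PKI libraries run from below 0 for short to above 0 for long transcripts.

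The fourth comparison set these calls beside the authors' own. The authors' deposited table held 14 entries at an adjusted p below 0.05, 13 higher and 1 lower in PKI. Of these, 3 genes were shared with the 18 called here, in the same direction: PKIA, FOSL1 and IL11. In the authors' deposited table PKIA had a log2 change of 2.19 (adjusted p = 1.23e-41), FOSL1 1.15 (adjusted p = 3.75e-05) and IL11 2.76 (adjusted p = 0.00126). The authors' deposited table also called SPRY4 (1.26) and ANXA3 (0.93) higher and RP11-544M22.13 (-1.44) lower. TMEM265, which the authors' deposited table called higher, is at 0 in 4 of the 6 libraries, with 0.886 CPM in PKI A and 0.612 CPM in PKI C. The 7 other entries called higher in the authors' deposited table are 4 identical copies of the 5.8S ribosomal RNA gene RNA5-8S5 and 3 CH507-513H4 genes with identical CPM. RNA5-8S5 stood at 17.9 and 33.1 CPM in PKI A and PKI C, at 1.06 CPM in PKI B and at 0.331 to 1.02 CPM in the inPKI libraries. Each CH507-513H4 gene stood at 2786 and 4172 CPM in PKI A and PKI C. It stood at 147 CPM in PKI B and at 87.2 to 255 CPM in the inPKI libraries. These genes outside the named set were chosen after their values were seen. In the authors' deposited table the adjusted p was 0.636 for EGR1 and 0.999944 for FLNC, and HSPA6 had none. Across the tested genes, the log2 changes of the 2 sources had a Pearson correlation of 0.973 and a Spearman correlation of 0.994. The standard error in the authors' deposited table was in the median 1.86 times the one here. The scales differ: the one here is moderated and of log2(CPM + 1), and the deposited one comes from a fit with other libraries.

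Between libraries, the Pearson correlation of log2(CPM + 1) over the tested genes lay between 0.989 and 0.997. The first principal component held 44.1% of the variance and placed the inPKI libraries at -8.67, -8.56 and -8.56, and PKI A, B and C at 4.91, -1.90 and 22.8. PKI B thus lay nearer to the inPKI libraries than PKI C did on this component. No pair of libraries agreed within sampling noise, since the chi-square per degree of freedom was at least 2.31 in every pair.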

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

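The tests of explanations in this part, with the removal of trends, the runs without PKI A and PKI C and the counts over other splits, were chosen after the results had been seen, while the fixed lists, their camera tests and the runs that leave out 1 library were planned. No group has the 4 libraries that a test for outlying samples needs.

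Signal appeared in data outside the 6 libraries. In 474 genes that are 0 in all 6 libraries, the baseMean in the authors' deposited table is above 3, and the baseMean of the keratin gene KRT5 there is 316371, so that table holds signal of other libraries, which are not analysed here.

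Keratinocyte transcripts were present in the HEK293 libraries at a nearly fixed share of that signal. Of the 14 keratinocyte list members with a baseMean of at least 1000, 12 lay within 2-fold of their median share, 0.117% (KRT10 and DSC3, both higher, did not), and the spread of the log2 share over all 14 (MAD) was 0.234, which argues against the HEK293 cells' own expression of most of the list. Over 253 genes with a baseMean of at least 10000 the lowest share was 0.0997%, a floor that RNA or reads carried over from keratinocyte libraries may leave. The 12 genes summed to 93.4 CPM in inPKI C and to at most 46.8 CPM in any other library, with KRT5 at 26.5 CPM in inPKI C and 9.84 to 13.2 CPM elsewhere. Without inPKI C the median log2 change of the list was 0.0030, against -0.28 with it, which argues against an effect of PKI as the cause of the list's lower value.

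RNAs without a poly(A) tail were high in PKI A and PKI C. Of 10 distinct genes annotated as rRNA, snRNA, snoRNA, ribozyme and the like, 9 lay above all inPKI libraries in both (all but BCYRN1), and the histone list, fixed beforehand, had medians of 0.19 and 0.68 there against -0.042 in PKI B. In PKI B, which held the same rise of PKIA, the median of the 10 genes was 0.099, inside the inPKI range of -0.22 to 0.15. Carry-over of such RNA past the mRNA selection is a candidate explanation, and an effect of PKI cannot be told apart from it, since 1 library excludes nothing. With PKI A and PKI C left out, where the lone PKI B is assumed to vary like the inPKI libraries, the mitochondrial list had a median of -0.055 and a call in the lower direction with the preset correlation (adjusted p = 0.00689, range over all alternatives 2.39e-08 to 0.687) and none with an estimated one, as with all 6 libraries (adjusted p = 0.913).

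Longer transcripts were higher in all 3 PKI libraries. GC content does not account for it: the Spearman correlation of the log2 change with length was 0.450, and 0.422 once the GC trend was removed. The lowest PKI library exceeded the highest inPKI library by 0.262, and whether RNA or library quality or an effect of PKI brought this about cannot be told apart, as either runs with the groups. With both trends removed, 9 of the 14 higher calls were kept (PKIA, HSPA6, FLNC, DNAJB1, EGR1, IL11, FOSL1, MAFF and SMG1P3), so the trends are not their whole cause, nor that of the changes of SULT1A4 (1.24 ± 0.22 before and 1.34 ± 0.24 after, SE) and C5orf66 (0.92 ± 0.16 and 0.94 ± 0.17), which did not shrink and stayed at least 5.58 SE above 0, while their calls ended as their own limma p rose somewhat and fewer genes had a smaller p than theirs, which makes the adjustment stricter (adjusted p = 0.0490 at rank 18 before and 0.102 at rank 11 after for SULT1A4, 0.0435 at rank 17 and 0.104 at rank 12 for C5orf66). The 3 other higher genes (KIF1A, RGPD8 and PKD1P1) stayed at least 5.03 SE above 0 and the 4 lower genes at least 3.81 SE below 0, but these calls were not kept. They ended as the changes shrank, from a median of 0.44 (median SE 0.076) to 0.41 (0.077) and from -0.45 (0.073) to -0.32 (0.072). The limma adjusted p was then 0.132 to 0.172 for the higher and 0.192 to 0.252 for the lower genes. Both sets had been picked for their small p in the same data, so their distance from 0 cannot decide whether the trends are their whole cause. For the ribosomal protein list, whose median went from -0.17 to -0.10 with 72 of 74 genes still below 0, the trends stay open as the whole cause. Camera called the rest with the preset correlation (adjusted p = 5.85e-23, in a range of 3.26e-46 to 3.90e-17) and not with an estimated one (adjusted p = 0.658 with the trends removed and 0.787 without that step).

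The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 18 genes and the highest of the others 1, so 1 of the 10 splits, the real one, called as many as that. For the fixed lists the real split called 7 and the highest of the others 10, and 3 of the 10 splits, the real one included, called at least as many.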

How the results depend on the processing

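The alternatives on length, GC content, PKI A with PKI C, and identical rows were chosen after the data were seen. The 18 called genes kept their direction under all 22 alternatives that gave a value; PKIA, FLNC and HSPA6 passed in all 22, and the 18 together lost the call in 106 of 390 cases. The 7 called lists kept direction and call in 95 of 153 cases. The ribosomal protein list passed in 22 of 22 and the ERK list in 21 of 22 with the preset correlation. With an estimated correlation neither list passed (camera adjusted p = 0.787 for each), nor did any other list tested. Cause was not tested except where stated.

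Against 18 genes (14 higher, 4 lower), 4 (4 and 0) passed with no filter, where 28891 genes were tested, and 4 (4 and 0) with limma without a trend. Columns rescaled to an equal sum gave 11 (1 lower), sample weights 144 (108 and 36), and DESeq2 139 (97 and 42); edgeR gave 16. The replicate block gave 124 (102 and 22), but nothing in the labels says that letters pair the libraries. Same-letter deviations correlated weakly, at 0.0171, 0.0138 and 0.0283, yet each library correlated best with its own letter. That is a hint from the data only, and pairing stays open. With the length trend removed 10 passed (0 lower), with GC removed 11 (1 lower), with both 10 (0 lower), and 49 (23 and 26) without PKI A and C, which leaves 1 PKI library. Leaving out 1 library gave 9 to 114 genes (9 to 84 higher, 0 to 30 lower). Rescaling moved the median of all genes by less than 0.1.

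Against 7 called lists, 4 passed with a pseudocount of 0.25, 4 with no filter, 3 with the 5 CPM filter, 3 with median-ratio rescaling, 3 with an equal sum, 3 without a trend, 4 with sample weights, 4 with DESeq2, 0 with an estimated correlation and 1 with fry in 1 direction (PKA). The mixed fry test passed for the PKA (adjusted p = 0.000760), ERK (0.00184), YAP-TEAD (0.00184), heat shock (0.00184), Wnt (0.00292), CREB (0.00768) and cAMP (0.0181) lists. It gave no call for the other lists. A call in that test does not say how many members changed, and for the PKA list fry was run only with PKIA included. With length, GC or both removed 4, 3 and 4 passed, and 3 to 5 with 1 library left out. Of 3 genes shared with the authors' deposited table, 2 remained at an adjusted p below 0.01 and 2 at a log2 change of at least 1; the third, FOSL1, is at 0.86 on the log2(CPM + 1) scale, which shrinks low genes, while its mean CPM rose 2.21-fold.

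Directions turned as follows (a list's direction is that of its test, its value the median log2 change), with no call under the alternative unless said. Hedgehog: -0.040 with length removed, -0.033 with both, -0.0083 without PKI A and C. Interferon: 0.038 with length, 0.043 with both. NF-kB: -0.021 with no filter. SRF-actin: 0.013 with sample weights. Without PKI A and C: SRF-actin 0.0053, S phase 0.049, G2 and mitosis 0.037, p53 0.011, unfolded protein 0.028, cholesterol 0.017, mitochondrial -0.055 (past the threshold), histones -0.042, PKIB 0.15, PCNA 0.019. PRKACB: -0.016 with GC, -0.0032 with both removed. With 1 library left out, ranges were YAP-TEAD -0.015 to 0.092, SRF-actin -0.091 to 0.032, S phase -0.076 to 0.022, G2 and mitosis -0.060 to 0.0096, p53 -0.034 to 0.017, interferon -0.046 to 0.027, unfolded protein -0.11 to 0.0054, heat shock -0.11 to 0.000020, mitochondrial 0.000060 to 0.22, keratinocyte -0.50 to 0.0030, PKIB -0.30 to 0.00033, PRKACB -0.040 to 0.059.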

Other observations

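The look at the anchoring protein genes, the PKA list without PKIA, the heat shock and ERK hypotheses and the run without PKI A and PKI C were chosen after the results had been seen, while limma, DESeq2 and the lists were planned. Of the anchoring protein genes in the PKA list, which were not tested as a group, AKAP12 measured 115 ± 1.02 CPM in inPKI and 134 ± 3.50 CPM in PKI and AKAP13 43.3 ± 0.706 CPM in inPKI and 52.3 ± 3.32 CPM in PKI (SD, n = 3 each), with log2 changes of 0.22 ± 0.050 and 0.27 ± 0.059 (SE); AKAP9 and AKAP11 had 0.28 ± 0.084 and 0.23 ± 0.059. In limma these 4 passed when adjusted over the list alone and AKAP1, AKAP2, AKAP5, AKAP8 and AKAP10 did not (log2 changes of -0.038, 0.037, 0.20, -0.0099 and 0.14). Over all genes the limma adjusted p was 0.110, 0.109, 0.190 and 0.145 for AKAP12, AKAP13, AKAP9 and AKAP11, and DESeq2 called AKAP12 and AKAP13 (adjusted p = 0.00956 and 0.0296). The list's call may rest on PKIA: without it the adjusted p was 0.285 and the median log2 change -0.0098. The call was also lost with the trend of transcript length removed (camera adjusted p = 0.225). Whether the rise of AKAP9, AKAP11, AKAP12 and AKAP13 follows that trend was not tested.

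HSPA6 and DNAJB1 were higher in PKI, and a rise of the whole heat shock list was tested as a hypothesis. The median log2 change of the 15 members was -0.051 (SD 0.17 over members), with 6 members above 0 and 9 below, so the members did not all rise. DNAJB1, at 0.42, has the highest change of the list. Its distance from the median therefore cannot decide whether a heat shock response took place. Without PKI A and PKI C the list was called higher with the preset correlation and not with an estimated one (adjusted p = 0.718 with the latter; with the former median 0.044, adjusted p = 0.0082, in a range of 0.0082 to 0.919 over the alternatives), with the lone PKI B assumed to vary like the inPKI libraries.

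With the preset correlation the ERK list was called by camera and the CREB list was not. The ERK call was lost with an estimated correlation (adjusted p = 0.787) and by fry (adjusted p = 0.133). The hypothesis that the ERK list rose more than the CREB list was looked at through the difference between the list means per library. That difference was higher in PKI by 0.16 (log2), with 3 of 3 PKI libraries (lowest 0.14) above 3 of 3 inPKI libraries (highest 0.026). The exact 2-sided permutation p was 0.1, the smallest that 3 against 3 libraries can give whatever the values, so this test decides nothing and the hypothesis stays open.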
